A study of Homo sapiens with 8 samples.

How the data were processed

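RNA sequencing was done on total RNA, prepared with TRIzol per the labels' protocols, from KARPAS-422 cells in 8 libraries: DMSO, CPI360, EPZ6438 and GSK126 with 2 each. Groups and replicate numbers came from the sample titles. TopHat 1.4.1, Cufflinks and the genome build hg19 are named in the submitters' processing notes. The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, in 1 table with a row per Ensembl gene; the unit was inferred from the tools and the values, since the file header does not name it. The library kit, strand, annotation release, aligner settings and Cufflinks version are not given in the sources used here. Without strand information, a gene and an antisense partner cannot be told apart, and Cufflinks divides reads between copies by estimate. Gene types came from GENCODE release 29 by Ensembl ID and were used only to count classes of genes; coordinates are those of the table.

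Each record of the table spans 2 lines because its last field ends in a quoted line break, so records were parsed as quoted fields. After parsing, the 8 columns held 63129 cells each, 0 that were neither a number nor NA, 0 below 0, and between 9 and 20 NA. The automated line-by-line check of units cannot read such records, so its range check for FPKM was repeated on the parsed records. The table has 56225 distinct symbols, 5756 rows on alternate or patch sequences and 44 rows with an NA in at least 1 library, which were left out of tests. All 37 mitochondrial rows are listed at 0. FPKM keeps no read totals. The sums were 435992 to 464762 FPKM. Relative depth was read from the most frequent ratio of low values (both under 0.05 FPKM) to those of DMSO replicate 1, within 0.01 on the log2 scale; 15.1 to 16.9% of 2754 to 2929 genes lay at that step. It was 0.840 for DMSO replicate 2, 0.924 and 1.01 for CPI360, 0.995 and 1.15 for EPZ6438 and 0.959 and 0.950 for GSK126, so depths were similar and absolute depth is unknown.

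Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), a pseudocount of 1, with a trended empirical Bayes prior and all 8 libraries in 1 fit of group means, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with at least 1 FPKM in 2 or more libraries were tested, 15102 rows. The residual degrees of freedom were 4 and the prior added 5.48; the median residual SD was 0.109 on the log2 scale. Each inhibitor and their mean were compared with DMSO, each pair of inhibitors was compared, and a moderated F test asked for any difference among the inhibitors. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, on lists with 3 or more tested members. By fry the interferon list was directional in the mean comparison (adjusted p = 5.56e-06). So were the MHC class I (0.000476), stress response (0.000507), cholesterol (0.000519) and proliferation genes (0.00201). Fry does not compare a list with other genes, and it also passed many lists that camera did not call. A symbol with several rows was used once, by its row with the highest mean.

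The tests, groups, 24 gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls of the mean comparison and the 5 largest in each direction of the others, among called genes whose groups did not overlap, up to 4 members per list with the smallest p, and EZH2, ABAT, TNFRSF21, TXNIP, PRDM1 and CDKN1A; it left out placeholders, small RNAs, pseudogenes, antisense and intronic transcripts by name, antigen receptor segments, XIST and Y-linked genes. Further list members named in the report for their direction were chosen after their values were seen, and some list members are not reported here. The lists were PRC2 subunits, germinal centre, plasma cell, B cell activation, B cell receptor signalling, MHC class I and II, proliferation, cyclin-dependent kinase inhibitor, p53 target, cell death, interferon response, NF-kB target, cholesterol, lysosome, stress response, xenobiotic response, developmental transcription factor, histone and ribosomal protein genes, mitochondrially encoded genes, and markers of T and NK, myeloid, and epithelial or mesenchymal cells.

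The fit was tested on simulated data for 15102 genes with the moderated spread of the real fit, where 50 genes per fold size were changed. In the mean comparison it recovered 24% of the smallest simulated changes, estimated at a median of 1.24-fold, 96% of 1.5-fold, 100% of 2-fold and 98% of 4-fold changes with 16 false calls, and for CPI360 against EPZ6438 6%, 78%, 100% and 100% with 6 false calls. For simulated lists in the mean comparison, 1 of 1 list shifted by 1.5-fold and 0 of the unshifted lists were called, both with the preset and with an estimated correlation. The simulated noise had the same spread in all groups, whereas the real DMSO replicates differed more than the others. Recovery and false calls may therefore look better in the simulated comparisons with DMSO than they are in the real ones. The noise was also independent between genes. In the real lists the estimated correlation was higher than the preset, such as 0.265 for interferon and 0.388 for proliferation genes. The simulation therefore cannot show how often camera at its preset calls such correlated lists falsely. Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, median rescaling and quantile normalization between libraries, other priors, a fit of only the groups compared, the replicate number as a block, and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.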

Results

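RNA was sequenced from KARPAS-422 cells, an established line of diffuse large B cell lymphoma, after treatment with 1 of 3 inhibitors of EZH2, the methyltransferase of the Polycomb repressive complex that methylates histone H3 at lysine 27. CPI360, EPZ6438 and GSK126 were each given at 1.5 µM for 4 days, and cells with DMSO, the solvent, served as controls. The labels give no day for the DMSO cells. A difference in culture time can therefore not be told apart from an effect of the inhibitors. Each of the 4 groups had 2 libraries, 8 in all. The deposited values were FPKM for 63129 annotated genes, which give no read totals. The smallest steps between low values put the depth of the other libraries between 0.840 and 1.15 times that of DMSO replicate 1, the shallowest being DMSO replicate 2 and the deepest EPZ6438 replicate 2. Between 14053 and 14618 genes reached 1 FPKM in a library, and 15102 genes were tested. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The first principal component of the tested genes held 82.6% of the variance and separated the DMSO libraries, at -50.7 and -59.2, from the inhibitor libraries, which lay between 11.8 and 24.1. The DMSO libraries also differed from each other more than any other replicates, with a standard deviation of 0.254 for their log2 difference, against 0.167 to 0.193 in the inhibitor groups. The fit shares 1 spread per gene among the groups. It may therefore understate the error against DMSO and overstate that between inhibitors.

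The first question was what inhibition of EZH2 did to the transcripts of its own complex and to genes of special interest. EZH2 mRNA itself (ENSG00000106462, hg19 chromosome 7, 148504474 to 148581413) fell from 51.7 ± 4.18 FPKM in DMSO (SD, n = 2) to 33.2 ± 2.15 FPKM over the inhibitor libraries (SD, n = 6), a log2 change of -0.62 with an SE of 0.08 (limma, adjusted p = 8.2e-05). Among 11 measured subunits of the complex, 3 rose, 5 fell and 3 did not pass, both over all genes tested and when adjusted over the list alone. JARID2, a targeting subunit, rose 2.24-fold, whereas AEBP2 fell to 0.65 of its DMSO level. ABAT, a transaminase that degrades the neurotransmitter GABA, rose from 1.77 ± 0.208 to 15.3 ± 1.46 FPKM, 8.65-fold (adjusted p = 1.42e-08). PRDM1, which encodes the plasma cell regulator Blimp-1, rose from 0.129 ± 0.0679 to 1.48 ± 0.197 FPKM (adjusted p = 4.58e-06). TXNIP, an inhibitor of thioredoxin, fell by 1.02 on the log2 scale (adjusted p = 0.00105), with 395 and 751 FPKM in the DMSO libraries and 268 ± 18.3 FPKM over the inhibitor libraries. TNFRSF21, a death receptor, stood at 0.0151 ± 0.0054 FPKM in DMSO and 0.726 ± 0.262 FPKM with inhibitors, below the level needed for a test. CDKN1A, the cell cycle inhibitor p21, gave 4.66 ± 0.831 FPKM in DMSO and 3.84 ± 0.891 FPKM with inhibitors, which did not pass the test (adjusted p = 0.0862), although it passed with quantile normalization (adjusted p = 0.0349) and without DMSO replicate 1 (adjusted p = 0.0266). PRC2 genes as a list were not called by camera, limma's test of gene lists (adjusted p = 0.623).

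The second question was what the inhibitors had in common, from the mean of the 3 inhibitor groups against DMSO. Genes of the type I interferon response dominated the rises. All 29 tested members of this list rose, over all genes and when adjusted over the list alone, with a median log2 change of 3.22. IFI27 (hg19 chromosome 14, 94571181 to 94583033), an interferon-induced mitochondrial protein, rose from 2.09 ± 0.37 FPKM (SD, n = 2) to 161 ± 67.6 FPKM (SD, n = 6), 77.3-fold (adjusted p = 1.59e-09). IFIT1, which binds foreign RNA, rose 46-fold, OASL 32.4-fold, RSAD2, the antiviral enzyme viperin, 21.4-fold, and ISG15, a ubiquitin-like modifier, 14-fold to 1817 ± 280 FPKM. The largest 12 rises also held IFI6, IFIT3, XAF1, USP18 and IFI44L of that list, with the glycan-binding protein genes LGALS9, 86.9-fold, and LGALS3BP, 16.4-fold. LGALS9 stood at 0.392 FPKM in DMSO, so its fold rests on a low value. Its log2 change as tested was 4.58, against 5.61 for IFI27. USP18 has near-identical copies in the genome, so its reads may be split between them. The list was called by camera (adjusted p = 2.85e-24). With a correlation estimated from the data the adjusted p = 0.344, and no list of this comparison was called in that setting. That setting relies on 4 residual degrees of freedom. Even this list, with all 29 members higher, had an unadjusted p of 0.015 there by camera. The same setting did call the simulated list shifted by 1.5-fold, where noise was independent between genes. For the real interferon genes the estimated correlation was 0.265. A missing call with an estimated correlation therefore does not show that a list is unchanged, but no list was called under both settings.

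**Figure D1:**
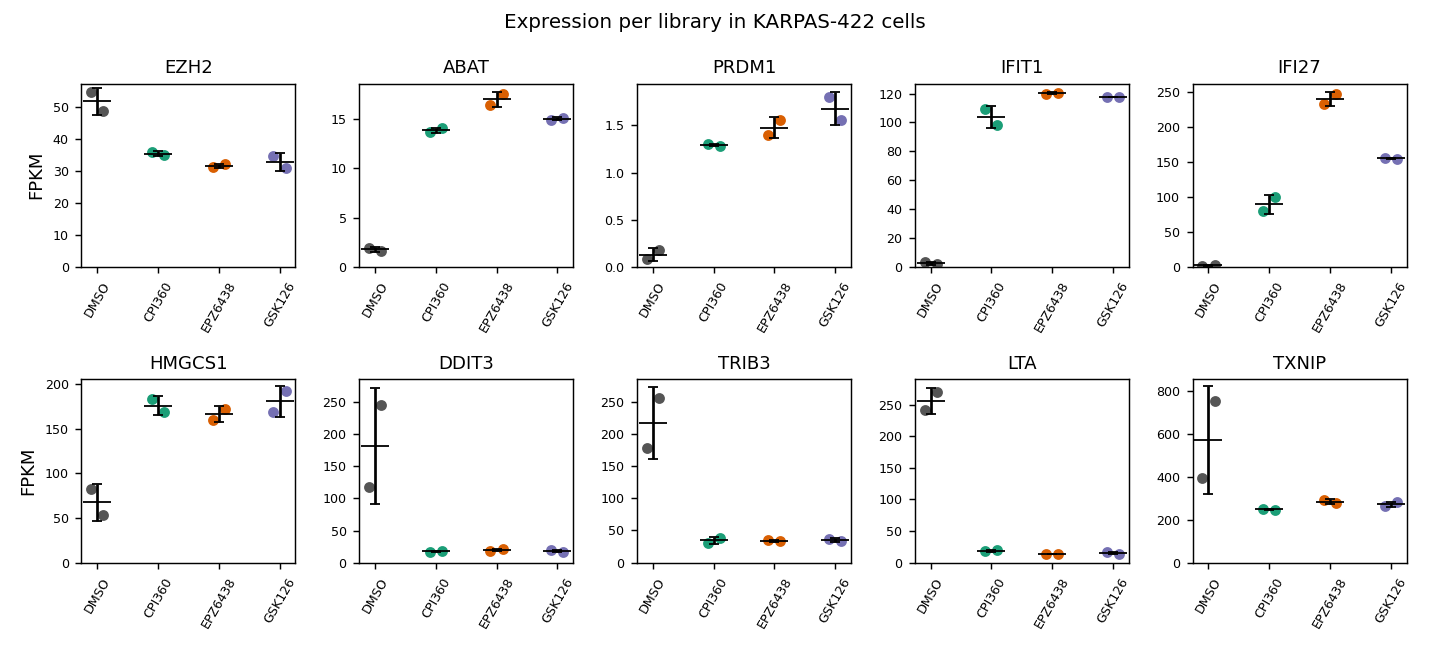
FPKM of 10 genes in each of the 8 libraries (points), with the mean and SD of each group of 2 (black); every axis starts at 0. EZH2, DDIT3, TRIB3, LTA and TXNIP are lower in the inhibitor libraries than in both DMSO libraries, and the other 5 genes are higher.

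MHC class I presentation genes rose with the interferon response genes. Of 15 tested, 14 rose and 1 fell, the peptidase ERAP2, with the same counts when adjusted over the list alone. HLA-F rose 5.17-fold, the peptide transporter gene TAP1 2.88-fold and HLA-B 2.42-fold, from 413.6 ± 60.5 to 1000.0 ± 152 FPKM (adjusted p = 8.13e-06); reads of HLA genes are shared between related genes and alternate haplotypes, so their levels are uncertain. Camera called this list (adjusted p = 9.45e-06), but not with an estimated correlation (adjusted p = 0.448). MHC class II presentation genes moved both ways, with 5 rises and 6 falls among 15 tested: HLA-DOA rose 2.75-fold and CD74, the invariant chain, 1.68-fold, while HLA-DMB fell to 0.469 of its DMSO level. The class II list was not called (adjusted p = 0.963), and its median of -0.02 and mean of 0.02 have opposite signs, the median turning to 0.04 with median rescaling and 0.01 with quantile normalization.

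On the log2 scale LTA, which encodes the cytokine lymphotoxin alpha, fell most among the named genes. OGN came next, with a log2 change of -3.43, at 0.0344 of its DMSO level. DDIT3, TRIB3 and SESN2 of the stress response list were also among the 12 largest falls. LTA (hg19 chromosome 6, 31539830 to 31542101) fell from 256.3 ± 20.5 to 15.8 ± 2.48 FPKM, 0.0615 of its DMSO level (adjusted p = 3.53e-09), and its neighbour TNF fell to 0.171; both lie in the MHC region, which the annotation also holds on alternate sequences. Of 22 stress and unfolded protein response genes, 16 fell, 5 rose and 1 did not pass, and the counts were the same when adjusted over the list alone. DDIT3, a transcription factor of this response, fell to 0.102 of its DMSO level, where its replicates gave an SD of 90.6 around 182.2 FPKM. TRIB3, an ATF4 target, fell to 0.159, the leucine sensor gene SESN2 to 0.181, CHAC1, which degrades glutathione, to 0.185, and PSAT1, an enzyme of serine synthesis, to 0.299. The 5 that rose were HSPA5, HSP90B1, PDIA4, CRELD2 and MANF, all of which act in protein folding in the endoplasmic reticulum. The list was lower as a whole by camera (adjusted p = 0.00139), and was not called with an estimated correlation (adjusted p = 0.523). Other genes among the 12 largest falls were OGN, INHBE, CEBPB, CCPG1, GDAP1L1, ATF5 and WARS, the last a tRNA synthetase that fell to 0.19 of 572.9 ± 93.7 FPKM. CCPG1 overlaps other annotated transcripts, so its level is uncertain.

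Cholesterol synthesis and uptake genes rose together: 22 of 24 tested rose, 1 fell and 1 did not pass, the same when adjusted over the list alone. LSS, lanosterol synthase, rose 3.75-fold from 10.45 ± 0.393 FPKM (adjusted p = 2.56e-07), DHCR7, the last enzyme of the pathway, 3.66-fold, and INSIG1, the sterol-regulated inhibitor of the pathway, 3.27-fold. PMVK was the member that fell. Camera called the list (adjusted p = 5.03e-09), and did not with an estimated correlation (adjusted p = 0.448).

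Proliferation genes fell in 24 of 30 cases and rose in none, over all genes and when adjusted over the list alone, and 6 did not pass. E2F1, a transcription factor of the G1 to S transition, fell to 0.347 of its DMSO level, from 42.98 ± 0.574 to 14.9 ± 1.14 FPKM (adjusted p = 6.73e-07); BIRC5, which encodes survivin, fell to 0.425 and AURKA to 0.513. Camera called the list (adjusted p = 8.18e-07), and did not with an estimated correlation (adjusted p = 0.523). Among 6 cyclin-dependent kinase inhibitor genes 1 rose, CDKN2C, and 4 fell, led by CDKN1B at 0.498 of its DMSO level; the list was not called (adjusted p = 0.266). Without DMSO replicate 2 the log2 changes of CDKN2A and CDKN2B were -0.392 and -0.277, against -0.51 and -0.448 with all libraries, and neither kept its call. CDKN2A also lost its call with no filter on low values, at an unchanged log2 change (limma adjusted p = 0.0832). Replication-dependent histone genes gave 10 rises and 2 falls among 17, and 11 rises and 2 falls when adjusted over the list alone. HIST2H2BE rose 6.17-fold, from 0.404 to 2.5 FPKM, a log2 change of 1.295 as tested. HIST1H3B fell to 0.129 of its level, from 1.23 to 0.158 FPKM, a log2 change of -0.939 as tested. The list was called (adjusted p = 0.0185), though not with an estimated correlation (adjusted p = 0.610). Ribosomal protein genes, fixed as a sign of RNA quality, fell in 20 of 30 cases, with the same count over the list alone, and moved with the groups above: the median log2 change was -0.30, and RPL5 fell from 962.3 ± 47.8 to 557.1 ± 46.1 FPKM. With median rescaling 1 rose and 17 fell, and with quantile normalization 1 rose and 16 fell. Camera called them (adjusted p = 3.62e-04), not with an estimated correlation (adjusted p = 0.546). The 15 mitochondrially encoded genes were listed at 0 in all libraries, so they gave no test.

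Among the lists of B cell stages and B cell signalling, camera called the plasma cell genes only. Of 15 tested plasma cell genes 10 rose and 2 fell, and 11 rose and 2 fell when adjusted over the list alone. IGJ, the joining chain of secreted antibody, rose 4.58-fold, FKBP11 2.28-fold and PRDM1 11.5-fold, whereas XBP1, a transcription factor needed for antibody secretion, fell from 69.52 ± 7.12 to 19.15 ± 0.812 FPKM (adjusted p = 1.76e-07). This list was called (adjusted p = 0.0202), and not with an estimated correlation (adjusted p = 0.546). GSK126 replicate 1 was higher in some antibody and plasma cell genes, with IGLC3 at 25.1 FPKM against at most 7.23 FPKM in the other libraries and IRF4 at 0.697 FPKM against at most 0.243 FPKM, both named after their values were seen. Other plasma cell genes did not stand apart there: SDC1 gave 8.76 against at most 8.63 FPKM, and CD38 1.24 against up to 1.72 FPKM. The other libraries had 1 to 10 genes that stood out by a threshold given below, and this one had 8. Of 20 germinal centre genes 11 rose and 6 fell, the same over the list alone: BACH2, a repressor of plasma cell genes, rose 10.6-fold and SPIB 2.91-fold, while PAX5 and EBF1, regulators of B cell identity, fell by 0.82 and 0.71 on the log2 scale. The germinal centre list was not called (adjusted p = 0.112). All 6 tested B cell activation genes changed, 4 upward and 2 downward, the same over the list alone, with CD40 8.27-fold higher, and the list was not called (adjusted p = 0.157). Of 22 B cell receptor signalling genes 8 rose and 9 fell, the same over the list alone: PTPN6, a phosphatase that dampens the receptor, fell to 0.451, and PRKCB rose 2.44-fold. That list was not called (adjusted p = 0.795), and its median of -0.11 and mean of 0.05 differ in sign.

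The other lists fixed beforehand were mixed, and camera called only the myeloid markers among them. Of 16 NF-kB targets 7 rose and 5 fell, and 7 rose and 6 fell over the list alone, with CD40 and the chemokine gene CCL3 up and LTA and TNF down (adjusted p = 0.643 for the list). The median of 0.01 and mean of -0.09 of this list differ in sign. With median rescaling 7 rose and 3 fell, with a median of 0.06. Quantile normalization gave the same counts and a median of -0.05. Of 18 p53 targets 8 rose and 6 fell (9 and 6 over the list alone; list adjusted p = 0.623), with GADD45A 4.63-fold higher and TNFRSF10B at 0.537. Of 15 cell death genes 2 rose and 4 fell, the same over the list alone (list adjusted p = 0.438): BCL2 rose 1.48-fold, and PMAIP1 and BBC3, which promote cell death, fell to 0.459 and 0.33. Lysosome genes gave 10 rises and 3 falls of 24, the same over the list alone (list adjusted p = 0.118), with LIPA 2.41-fold higher; for EPZ6438 alone camera called them (adjusted p = 0.0338), and not with an estimated correlation (adjusted p = 0.552). Xenobiotic response genes gave 3 rises and 1 fall of 7, the same over the list alone (list adjusted p = 0.24), and the fall, GCLM, was lost without DMSO replicate 1 (adjusted p = 0.0993). Of 90 developmental transcription factor genes, a class often under Polycomb, 16 reached the level for a test, and 7 rose and 3 fell, the same over the list alone (list adjusted p = 0.223): SOX9 rose 7.52-fold and HOXC4 2.69-fold, while HOXB9 fell from 2.98 ± 0.592 to 0.0729 ± 0.0247 FPKM. Markers of other cell types were also measured. Of 6 tested T and NK cell markers 3 rose and 2 fell (list adjusted p = 0.689), NCAM1 rising 14-fold to 2.03 FPKM. Of 23 listed myeloid markers 3 were tested, and all 3 rose (list adjusted p = 0.0205, and adjusted p = 0.448 with an estimated correlation), CD68 by 4.1-fold to 4.85 FPKM. LYZ, at 0.418 FPKM in DMSO and 1.83 FPKM with inhibitors, reached the level for a test only through inhibitor libraries. Such genes can enter the test only as rises. Of 3 epithelial and mesenchymal markers 2 rose and 1 fell (list adjusted p = 0.539), but the fall, ACTA2, was lost without DMSO replicate 2 (adjusted p = 0.131) and a rise, FN1, was lost in 8 settings (adjusted p of 0.0513 to 0.507), 5 of which leave out a library: either DMSO library, CPI360 replicate 1, EPZ6438 replicate 2 or GSK126 replicate 2. DCN, which encodes decorin, stood at 421 ± 57.5 FPKM in DMSO and 817.4 ± 21.5 FPKM with inhibitors. For each of these 3 marker lists the counts were the same when adjusted over the list alone.

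**Figure D2:**
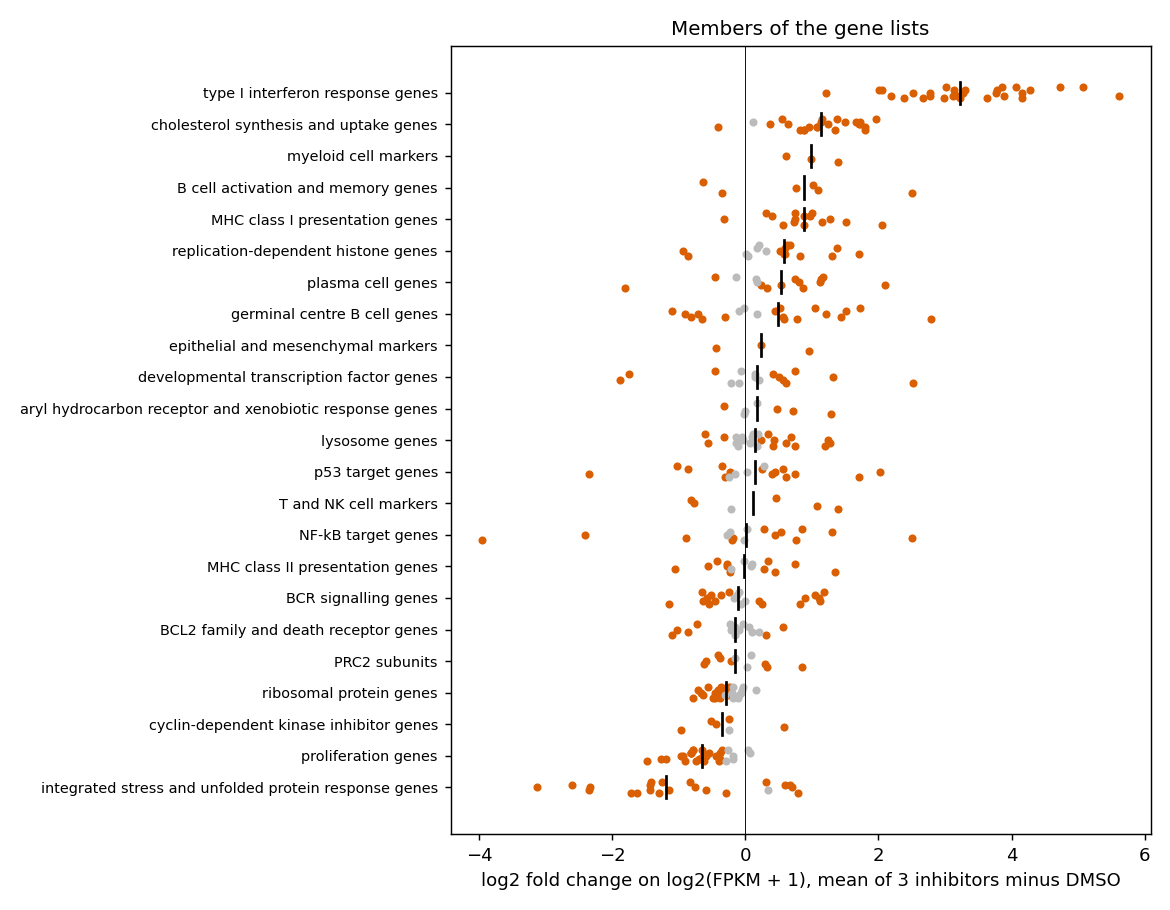
Log2 fold change of each tested list member, mean of 3 inhibitors minus DMSO, on log2(FPKM + 1) values; orange points passed an adjusted p of 0.05, grey points did not, and the black bar is the list median. The interferon response list has its median at 3.22 and the stress response list at -1.19.

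In numbers, 9492 of 15102 genes passed in the mean comparison (limma, Benjamini-Hochberg), 4534 higher and 4958 lower, and 1204 of them changed at least 2-fold, 806 higher and 398 lower. With median rescaling 5152 were higher and 4238 lower, and with no filter on low values 5408 and 4934. Folds are ratios of mean FPKM. Log2 changes and p-values were computed on log2(FPKM + 1), which understates the change of low genes. Processed pseudogenes, which share reads with their parent genes, made up 2217 of the tested genes and gave 302 rises and 898 falls.

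The third question was what each inhibitor did alone. The leading genes were alike: IFI27, IFIT1, IFI6, LGALS9 and OASL were the 5 largest rises and LTA, OGN, DDIT3, INHBE and CEBPB the 5 largest falls for every inhibitor. IFI27 reached 89.6 ± 13.8 FPKM with CPI360, 239.3 ± 10.1 FPKM with EPZ6438 and 155.0 ± 1.02 FPKM with GSK126 (SD, n = 2 each). LTA stood at 18.6 ± 1.24 FPKM with CPI360, 13.7 ± 0.261 FPKM with EPZ6438 and 15.03 ± 2.01 FPKM with GSK126. All 29 interferon response genes rose with each inhibitor, with median log2 changes of 3.11, 3.36 and 3.22, and camera's adjusted p with an estimated correlation was 0.269, 0.314 and 0.277. Cholesterol genes gave 22 rises and 1 fall with each, also when adjusted over the list alone, with an adjusted p of 0.464, 0.443 and 0.443 with an estimated correlation. Proliferation genes fell in 20 cases with CPI360, 25 with EPZ6438 and 23 with GSK126, and in 22, 26 and 23 when adjusted over the list alone, with an adjusted p of 0.542, 0.48 and 0.47 with an estimated correlation. CDKN1A was lower with CPI360 (2.92 ± 0.435 FPKM, adjusted p = 0.0102); with EPZ6438 it gave 4.77 ± 0.187 FPKM and with GSK126 3.82 ± 0.573 FPKM, and the difference between CPI360 and EPZ6438 did not pass (adjusted p = 0.195). By limma 7806 genes passed with CPI360 (3816 higher, 3990 lower), 8788 with EPZ6438 (4219 and 4569) and 8036 with GSK126 (3875 and 4161), of which 1049, 1428 and 1209 changed at least 2-fold. This balance depended on the setting. It turned with no filter on low values, where 3725 were higher and 3429 lower with CPI360, 4970 and 4204 with EPZ6438 and 4087 and 3668 with GSK126, and with median rescaling, where 4288 were higher and 3384 lower with CPI360, 4774 and 3811 with EPZ6438 and 4409 and 3538 with GSK126. For CPI360 it also turned with only the groups compared (3308 and 3213). Among protein-coding genes it turned for EPZ6438 (3288 and 3284) and GSK126 (3083 and 3047). Leaving out 1 particular library of its own turned it for each inhibitor, and for CPI360 leaving out DMSO replicate 1 did so too.

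The 3 responses overlapped. In all 3 comparisons 3386 genes were higher and 3499 lower, where independent lists of these sizes would share 274 and 333, and no gene passed in opposite directions in any pair. Across genes, which are not independent replicates, the log2 changes of CPI360 and EPZ6438 correlated with r = 0.967, those of CPI360 and GSK126 with r = 0.982 and those of EPZ6438 and GSK126 with r = 0.977. Because the comparisons share the DMSO libraries, unchanged groups simulated 50 times against shared controls gave a mean r of 0.499 and at most 0 genes called in all 3. The covariances of 0.352, 0.330 and 0.373 stood beside a simulated mean of 0.00775. The DMSO group is too small to split, so part of the excess overlap may come from the shared controls.

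The fourth question was whether the inhibitors differed at this matched dose and time. Single genes were lower with CPI360 than with EPZ6438. IFI27 was at 0.374 of its EPZ6438 level (log2 difference -1.41, SE 0.12, adjusted p = 0.0078) and LGALS9 at 0.433 (adjusted p = 0.0161), followed by ID3, an inhibitor of basic helix-loop-helix transcription factors, at 0.422, MVB12B, of the ESCRT sorting machinery, at 0.275 and PARVG, a cytoskeletal adaptor, at 0.42. Of 29 interferon response genes 3 passed as lower over all genes and 14 when adjusted over the list alone, with a median difference of -0.34; camera called the list (adjusted p = 6.59e-19), and did not with an estimated correlation (adjusted p = 0.261). Of the 30 proliferation genes 0 passed over all genes and 1 when adjusted over the list alone, as higher with CPI360 (median 0.24, list adjusted p = 6.47e-10, and adjusted p = 0.312 with an estimated correlation). At its preset correlation camera called 13 lists, among them as lower MHC class I genes (adjusted p = 3.11e-06, and 0.31 with an estimated correlation), histone and lysosome genes (each adjusted p = 5.67e-05, and 0.312) and NF-kB targets (adjusted p = 1.74e-04, and 0.261), and as higher the ribosomal protein genes (adjusted p = 0.00795, and 0.55). By fry, which asks only whether a list moves 1 way, the interferon and NF-kB lists passed (each adjusted p = 0.0461), while MHC class I (0.103), proliferation (0.173), histone and lysosome (each 0.179) and ribosomal protein genes (0.441) did not. Of these 5 lists, 1 MHC class I gene passed over all genes, and when adjusted over the list alone 5 MHC class I, 5 histone, 2 lysosome and 6 NF-kB genes did, 1 of the last as higher, and 0 ribosomal protein genes. In all 27 genes passed, all of them lower with CPI360, and 1498 had an unadjusted p under 0.05 (limma). The number of calls fell when any CPI360, EPZ6438 or GSK126 library was left out, and rose without either DMSO library. Neither GSK126 nor DMSO is part of this comparison, but all 4 groups share 1 estimate of the spread. Every such fit has fewer libraries, which alone cannot account for both the falls and the rises. The DMSO replicates differed more than those of any inhibitor, so leaving 1 out also changes the shared spread. The falls therefore cannot by themselves show that single libraries drive the calls. The direction was not always kept: 4 of the 5 calls without EPZ6438 replicate 1 were higher with CPI360, and with no filter on low values 10 of 27 calls were. IFI27 and the other 4 named genes kept their direction there but lost their calls without CPI360 replicate 1 or EPZ6438 replicate 2, and all but IFI27 also without CPI360 replicate 2 or EPZ6438 replicate 1. Their log2 differences stayed near the reported ones, from -1.26 to -1.37 for IFI27 and from -0.88 to -1.23 for the other 4 in those settings.

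CPI360 against GSK126 gave 0 calls, with 355 genes at an unadjusted p under 0.05, and EPZ6438 against GSK126 also gave 0 calls, with 635 (limma). Without GSK126 replicate 2 each of these gave 3 calls, and without EPZ6438 replicate 1 the second gave 3. Interferon response genes had a median difference of -0.15 for CPI360 minus GSK126, where 3 of 29 passed when adjusted over the list alone, and of 0.16 for EPZ6438 minus GSK126, where 1 of 29 did (limma). Camera called both (adjusted p = 9.48e-17 and 3.72e-09), and neither with an estimated correlation (adjusted p = 0.388 and 0.316). A missed threshold does not show that the compounds act alike. The 95% interval of the difference excluded a 2-fold change for 99.1% of tested genes between CPI360 and EPZ6438, 99.5% between CPI360 and GSK126 and 99.4% between EPZ6438 and GSK126, with a median half-width of 0.25 on the log2 scale. Among the 1204 genes changed at least 2-fold by the inhibitors these shares were 97.1%, 99.3% and 99.4%. On log2(FPKM + 1) a doubling of a low gene falls short of 1 unit, so low genes count as within 2-fold more readily. Any difference among the 3 inhibitors passed the moderated F test for 2 genes, IFI27 (adjusted p = 0.0294) and MVB12B (adjusted p = 0.0369), with 848 at an unadjusted p under 0.05 (limma). This number was 0 without CPI360 replicate 1, without EPZ6438 replicate 2 or without GSK126 replicate 1, 1 without CPI360 replicate 2 and 7 without GSK126 replicate 2.

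**Figure D3:**
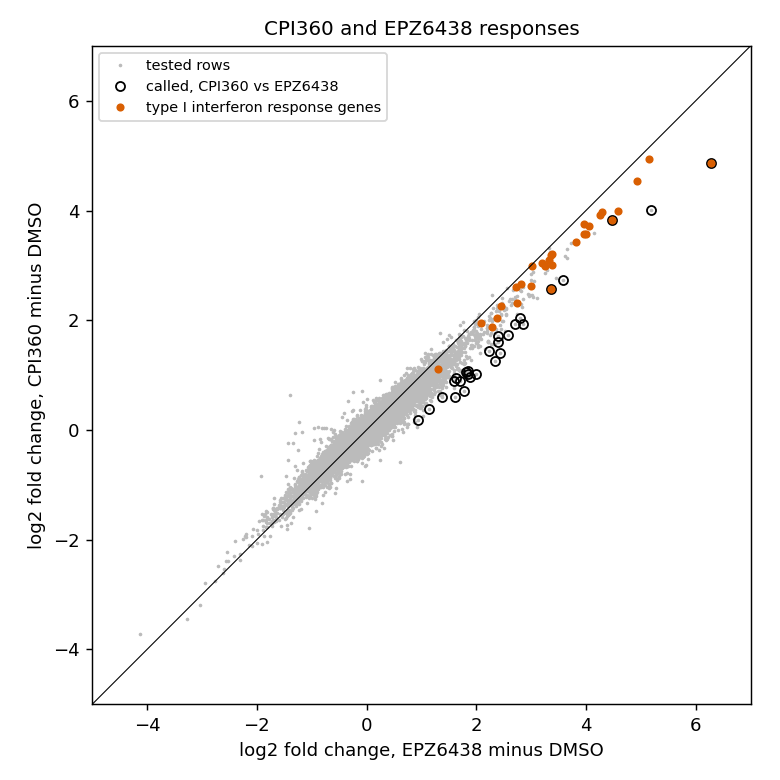
Log2 fold changes against DMSO with EPZ6438 (horizontal) and CPI360 (vertical) for the tested genes (grey), the interferon response genes (orange) and the 27 genes that passed between the inhibitors (open circles); the line marks equal change. The open circles lie below the line.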

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

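Genes with a missing value in at least 1 library stood outside every test, 44 in all, and 20 of them had both DMSO values and at least 3 inhibitor values. In 4 of these every inhibitor value lay above both DMSO values, and in 7 every inhibitor value lay below, in data that the comparisons did not use. These differences were not tested, and the genes were chosen after their values were seen. Shifts were also common among the tested genes, where by a different criterion 4534 of 15102 were higher and 4958 lower. GCH1, which makes the cofactor tetrahydrobiopterin, gave 76.6 and 103 FPKM in DMSO and 178 to 191 FPKM in the 3 inhibitor libraries with a value, and FAM219A gave 3.78 and 4.06 against 6.76 to 8.31 FPKM in 5. CAPRIN2 and SULT1A1 were the other 2, but the lowest inhibitor value of SULT1A1 was 41.7 against a highest DMSO value of 41.6 FPKM. Among those lower, EEF1B2, a translation elongation factor, gave 208 and 217 FPKM in DMSO and 122 to 151 FPKM in 5 inhibitor libraries.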

How the results depend on the processing

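All alternatives were fixed beforehand except the protein-coding subset, the crossed pairing and most settings of the overlap, which were chosen after seeing the data. The counts for the mean of the inhibitors and for each inhibitor against DMSO, and the overlap of all 3, stayed within 1.5 times under every setting except the demand for a 2-fold change, which left 1204, 1049 (CPI360), 1428 (EPZ6438) and 1209 (GSK126) by its construction. Over the settings that leave out 1 library, the counts ran from 8104 to 9212 for the mean, 5690 to 7954 for CPI360, 6562 to 8634 for EPZ6438 and 5951 to 8151 for GSK126, and the overlap of calls between inhibitors from 5253 to 7010; a group left with 1 library is assumed to vary like the others. Median rescaling moved the share of higher calls in the mean comparison from 47.8% to 54.9%, and from 48.9% to 55.9% for CPI360, 48% to 55.6% for EPZ6438 and 48.2% to 55.5% for GSK126, and the median change of all genes from -0.03 to 0.02. The share in the mean comparison was 52.3% with no filter and 42.7% with the filter at 5 FPKM; for CPI360 it was 50.7% with only the groups compared.

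The calls of CPI360 against EPZ6438, 27 as reported, were 2 with a pseudocount of 0.1, 17 with the filter at 5 FPKM, 43 with median rescaling, 80 for protein-coding genes only, 88 with only the groups compared and 6 at 2-fold, and ran from 0 to 36 when 1 library was left out. With no filter the number was again 27, but only 2 of the reported genes were among them and 10 were higher with CPI360, as were 3 of the 88. CPI360 against GSK126 went from 0 to 18 with no filter and ran from 0 to 3 without 1 library; EPZ6438 against GSK126 went from 0 to 17 with no filter and 2 with only the groups compared, and ran from 0 to 3. The F test, 2 genes as reported, gave 0 with a pseudocount of 0.1, 1 with 0.5, 29 with no filter, 1 with the filter at 5 FPKM, 7 with median rescaling, 6 with quantile normalization, 7 with the robust prior, 27 for protein-coding genes, 6 with only the groups compared, and 0 to 7 without 1 library. For these differences the cause was not tested. Only the groups compared is the same fit as reported for the mean comparison.

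With the replicate number as a block the calls were 9101 for the mean comparison, 7292, 8363 and 7563 for CPI360, EPZ6438 and GSK126 against DMSO, 18 for CPI360 against EPZ6438, 1 for the F test and 6428 for the overlap of calls between inhibitors. The numbers are not shown to pair the samples: deviations of same-numbered libraries correlated between -0.498 and 0.273 over the group pairs. Crossing the numbers of EPZ6438 and GSK126, a pairing chosen from those correlations, gave 10202 calls for the mean comparison, 22 for CPI360 against EPZ6438 and 1 for the F test. Camera called 9, 9, 10 and 9 lists for the mean, CPI360, EPZ6438 and GSK126 against DMSO, and 13, 9 and 10 between inhibitors, but 0 in each with an estimated correlation; the block and the pseudocount of 0.1 kept the counts within 1.5 times. Of 2570 alternatives for 142 named gene comparisons, 40 lost the call, 2 gained one and none reversed; most losses were the genes of CPI360 against EPZ6438 and FN1. IFI27, LGALS9, ID3 and PARVG lost theirs with no filter too, and LGALS9, ID3, MVB12B and PARVG with a pseudocount of 0.1 (adjusted p of 0.112, 0.0642, 0.0642 and 0.0736), where their log2 differences grew. CDKN1A passed in the mean comparison with quantile normalization and without DMSO replicate 1. Unknown depth limits what can be said of low genes, and simulations of CPI360 against EPZ6438 recovered 78% of 1.5-fold changes but 6% of the smallest, so differences of the size of the interferon list's median are mostly missed gene by gene.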

Other observations

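All tests of patterns here were chosen after the patterns were seen, and only the one of tRNA synthetase genes was written before its values were seen. The genes in this paragraph were chosen after their values were seen. They do not test any wider gene group. With inhibitors ZBP1, a nucleic acid sensor, went from 0.28 ± 0.0522 FPKM (SD, n = 2) to 10.6 ± 3.17 FPKM (SD, n = 6; limma adjusted p = 1.11e-08), AIM2, a sensor of cytosolic DNA, from 0.417 to 4.35 FPKM, TLR7 from 1.33 to 7.61 FPKM and the RNA editor ADAR from 96.8 to 206 FPKM. IFNB1, which encodes interferon beta, lay between 0.401 and 1.11 FPKM in every library and was not tested. IGKC, an antibody light chain gene, went from 924 to 2320 FPKM and IGHG1 from 210 to 623 FPKM, and of 24 tested immunoglobulin V segments 17 rose and 0 fell; reads of these copies may be split. AGR2, a protein disulfide isomerase, went from 0.122 to 9.23 FPKM and P4HA2, a collagen prolyl hydroxylase, from 0.0719 to 4.74 FPKM, whereas TNC, which encodes tenascin C, went from 2.31 to 0.0157 FPKM.

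GSK126 replicate 1 alone held more RNA of lambda light chain genes and of a few genes elsewhere, but by thresholds chosen after values were seen (at least 0.4 FPKM and 3 times every other library) it had 8 such genes, where the other libraries had 1 to 10. IGLV3-10 stood at 32.4 FPKM there and at 2.50 to 5.03 FPKM in the other 7 libraries, IGLC3 at 25.1 against at most 7.23 FPKM, FGFR3 at 0.968 against at most 0.257 FPKM and UCHL1 at 0.716 against at most 0.177 FPKM. A response to GSK126 and reads shared between light chain copies cannot be told apart from other causes: the median ratio of 1.13 between replicate 2 and the other 6 libraries follows from choosing genes low in replicate 2, and the 4 such genes on chromosomes other than 22 lie within the 1 to 10 that stood out in each of the others. RNA from plasma cell-like cells cannot be told apart either: of 11 low plasma cell and myeloma markers 45.5% were highest in this library, where chance gives 12.5%, between the bounds of 25% and 50%; SLAMF7 was 0.35 against at most 0.323 FPKM, CADM1 0.485 against at most 0.25 FPKM, and the abundant SDC1 8.76 against at most 8.63 FPKM. Without GSK126 replicate 1 the mean of 3 inhibitors vs DMSO gave 8897 calls.

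The fall of stress response genes may reflect the DMSO cultures as much as the inhibitors. The gap between the DMSO libraries does not account for it, since against the nearer of them all 22 tested genes of the list still had a median change of -1.11. A state shared by both DMSO cultures, such as amino acid shortage, cannot be told apart from an effect of the inhibitors, because the labels give no cell density or medium changes. All 11 tRNA synthetase genes examined, none of them in the list and WARS left out as already seen, were lower with inhibitors, with a median change of -1.07. The median gap of these genes between the DMSO libraries was 0.06. A state shared by both cultures would leave little gap, so this value does not count against it. An effect of EZH2 inhibition itself is untested.

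The lower values of interferon genes with CPI360 than with EPZ6438 are uncertain, since 3 of 29 passed and each group had 2 libraries. The list passed by fry (adjusted p = 0.0461). It was not called by camera with an estimated correlation (adjusted p = 0.261), a setting in which no list was called in any comparison. Most of the 27 calls between these inhibitors were lost when a library of either was left out, which also leaves that group with 1 library. The difference was not confined to low genes: all 27 interferon genes with a mean of at least 10 FPKM were lower with CPI360, with a median difference of -0.33. These make up nearly all of the 29 that showed the pattern, so their median had to repeat that of the list. It therefore does not test the depth of the EPZ6438 libraries separately. The slope of CPI360 on EPZ6438 changes was 0.896 for interferon genes (0.887 to 0.904 over the choices of 1 library per group, DMSO included), 0.859 for the genes at least 2-fold higher (0.824 to 0.889) and 0.937 for those at least 2-fold lower (0.911 to 0.950). A weaker response to CPI360 in all genes alike cannot be told apart from one that differs between gene groups, because 2 libraries per group give no firm spread for slopes this close. A difference in potency between the compounds remains a hypothesis that these data do not test.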
